A study of Mus musculus with 9 samples.

How the data were processed

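Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in 9 libraries of mouse LSK cells (lineage-negative, Sca-1-positive, Kit-positive haematopoietic stem and progenitor cells). Per the labels, 50000 cells went into each library, tagmentation ran for 30 min at 37 °C, the libraries were amplified over 10 cycles, and fragments of 170 to 800 bp were enriched. The groups were WT (n = 2), Bcat_KO (β-catenin, n = 2), HOXA9_KO (n = 2), PRMT1_KO (n = 2) and dKO (β-catenin and Hoxa9, n = 1). The sample titles call the mutants KO and the genotype tags call them knockdown, and the names of the titles are used here. The series text names only Prmt1KO transplanted mice as the source of the cells, and the labels do not say whether the WT and the other mutants came from transplants. They also do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these samples.

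Per the submitters' processing notes, the authors aligned the reads with Bowtie2 2.4.2 to GRCm38/mm10, handled them with SAMtools 1.14 and Picard 2.27.4, and called peaks with MACS2 in each library alone. The peak names show that unmapped reads and duplicates had been removed. The deposited peak lists held, for each peak, a score equal to the whole part of 10 times the −log10 q-value. They also held the authors' fold enrichment at the summit, a ratio of the pileup to the local background. The −log10 p-values and −log10 q-values deposited with each peak came from MACS2, and the lowest −log10 q-value in each list was 1.00 or 1.01 after rounding. The peak names of the dKO list follow another naming of the sequencing run than those of the other 8, so run and genotype cannot be separated for the dKO. The other deposited value was the summit offset, in bases from the peak start. No normalization between libraries enters these values, so fold and p were used only to describe a peak and to rank peaks within 1 list.

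The lists give no read totals. Fold and p together fix the number of reads at a summit and the background expected there, and the recovered reads were whole within 0.01 for 99.99% of the peaks or more in every library. The background at the floor of each list, divided by the shortest peak of the list, which MACS2 by default sets to the fragment length, gave a background depth in reads per kb. This depth is inferred, ignores reads removed before peak calling, and ranged from 2.41 to 11.2 reads per kb. A missing peak can therefore mean a region not detectable at the depth of that library. The precision of each group value is limited by the 2 libraries behind it. For shares of regions in the single dKO library, 95% Wilson intervals are given, and they cover counting error only.

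Peaks of all 9 lists that shared at least 1 bp were merged into 76253 regions. No filter for repeats or for sequence that maps poorly was applied to them here. Each of the 8 lists of the 4 groups with a pair was shortened to its 28325 strongest peaks by −log10 p, the length of the shortest list. A region was called closed in a mutant when it was among the strongest 14162 peaks of both reference libraries and outside the strongest 28325 of both mutant libraries, and opened in the reverse case. With 2 libraries against 2, no single region can reach a p under 0.333, so no p is given per region. The count was set beside the counts of both mixed splits of the same 4 libraries, in which each side holds 1 library of each group, and beside 100 simulated sets of libraries with no group effect. For the comparisons between mutants, the simulated counts were added after the results were seen, and so was the simulated overlap on autosomes. Regions of a single group were counted in the same way against the other 6 libraries.

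Differences between groups in peak number, in the share of peaks near genes and in depth were tested by an exact permutation test over all ways to divide 8 libraries into 4 pairs, with the between-pair sum of squares as the statistic. The same divisions served for the mean Jaccard index within pairs (shared regions over all regions) and for the number of group-specific regions. The smallest p these divisions allow is 0.00952. The number of regions that set WT or another pair apart was compared with all 28 choices of 2 libraries from 8. The similarity among mutants was compared with 45 assignments of the 6 mutant libraries to 3 pairs with a most alike pair. Overlap of changed regions between mutants was set beside the product of the shares and beside the same simulated libraries, in which the mutants shared their WT libraries. Fisher's exact test (two-sided, across regions) compared dKO peaks at opened and closed regions, with Benjamini-Hochberg adjustment over the 6 comparisons. Peak number and depth were related by Pearson's and Spearman's coefficients with permutation p over all pairings, adjusted in the same way over the 2 coefficients of the 8 libraries. All p-values of divisions are one-sided in the sense that only larger statistics count.

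Regions were placed with the RefSeq annotation of the same build and 20147 protein-coding genes. The annotation used here gives gene spans without strand, so a region counted as near a gene end when it lay within 1 kb of either end of a gene, in place of the transcript starts named in the design. Exons and UTRs were not distinguished. A region was given the nearest protein-coding gene within 50 kb, without predicted genes known only by a Gm number or Rik name.

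The main thresholds, tests, comparisons, 18 gene lists and the rule for named genes were fixed before the data were examined. The rule named the targeted genes Ctnnb1, Hoxa9 and Prmt1. For each mutant against WT it also named list members with a closed or opened region at or nearest to them within 50 kb, up to 6 per direction, and the 8 closed and 8 opened regions with the strongest mean rank. The 8 were taken among regions with a named gene within 50 kb. Regions without such a gene that ranked among the 8 strongest of all regions are given by position for the mutants against WT, a step added after the data were examined. The same rule was applied to the comparisons between mutants after the data were examined. Of 362 list genes, 360 were matched to the annotation, 1 of them by a synonym. For each list, mutant and direction, the number of genes with a changed gene end was compared with 10000 random lists of the same size, matched on rank, over 108 tests. Results at some of the genes that the rule names are not reported here.

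Alternatives fixed in advance were the lists as deposited, a list length halved for stricter peaks, no gap between the cutoffs, ranking by fold, merging of summits within 100 bp, autosomes alone, divisions that pair libraries with different replicate numbers, a −log10 q-value of at least 5, touching peaks counted once, other windows around gene ends, and leaving out each library. Absence from the full lists and tests without the WT libraries were added after the data were seen. The region rule was tested on simulated data made from a HOXA9_KO against WT comparison, where it recovered 73 of 100 closed and 72 of 100 opened regions, with 3 and 2 false calls. Motif tests were not run, because no genome sequence was used here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.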

Results

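Open chromatin was mapped by ATAC-seq in 9 libraries of mouse LSK cells, the fraction that holds haematopoietic stem cells and early progenitors. WT, Bcat_KO, HOXA9_KO and PRMT1_KO had 2 libraries each, and the dKO of β-catenin and Hoxa9 had 1, so values of the dKO carry no replicate error. β-catenin is the transcriptional effector of canonical Wnt signalling, Hoxa9 is a homeobox transcription factor of stem and progenitor cells, and Prmt1 is the main enzyme of asymmetric arginine dimethylation. The series asks how β-catenin and Hoxa9 support replication and stem cell function, and what part Prmt1 has in this. The libraries held 35581 and 28325 peaks in WT, 43250 and 45460 in Bcat_KO, 39885 and 41349 in HOXA9_KO, 44513 and 39881 in PRMT1_KO, and 10639 in the dKO. Background depth was 7.38 and 6.29 reads per kb in WT, 9.61 and 9.82 in Bcat_KO, 8.27 and 8.67 in HOXA9_KO, 11.2 and 10.9 in PRMT1_KO, and 2.41 in the dKO. Depth differed between the 4 groups with a pair by more than between the libraries of a pair (exact permutation p = 0.00952, the smallest that all divisions into pairs allow).

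The loci of the targeted genes were compared to see what the peak lists show at them. Ctnnb1 (GRCm38, chromosome 9, 120933400 to 120960507), the gene of β-catenin, had a peak at a gene end in all 8 libraries of the paired groups. Its strongest peak reached 8.33 ± 0.023 (SD, n = 2) times the local background in WT and 8.98 ± 0.293 (SD, n = 2) times in Bcat_KO. Prmt1 (chromosome 7, 44976755 to 44986420) had a strong peak at a gene end in every library, with a fold over background of 13.1 ± 1.80 (SD, n = 2) in WT, 16.9 ± 1.04 (SD, n = 2) in PRMT1_KO and 6.99 in the dKO. Hoxa9 (chromosome 6, 52223097 to 52227370) had a weak peak in its body in 7 of the 8 libraries, at 4.77 ± 0.449 (SD, n = 2) times background in HOXA9_KO and 4.78 in the WT library that had it. No peak was detectable at Ctnnb1 or Hoxa9 in the dKO at its depth. The labels do not give the deleted part of a gene, so these peaks do not test the deletions, and fold values were not normalized between libraries.

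The single mutants had more accessible regions in their lists than WT. The 6 single-mutant libraries held 42389.7 ± 2380.1 (SD, n = 6) peaks and the WT libraries 31953 ± 5131 (SD, n = 2), and no mutant library lay below 39881. By group, the means were 44355 ± 1563 in Bcat_KO, 40617 ± 1035 in HOXA9_KO and 42197 ± 3275 in PRMT1_KO (SD, n = 2 each). The division by genotype did not pass the exact permutation test (p = 0.0667, with 7 divisions as large), and with a stricter −log10 q-value of at least 5 it did (exact permutation p = 0.0381). Both WT libraries were also the shallowest of the 8. Across the 8 libraries, peak number rose with background depth by Pearson's r = 0.825 (exact permutation p = 0.0122, adjusted p = 0.0244) but not clearly by Spearman's rho = 0.714 (exact permutation p and adjusted p = 0.0576). Without the 2 libraries farthest in depth, WT replicate 2 and PRMT1_KO replicate 1, r was 0.588 and rho 0.429, so the relation rests on those samples. Within the 6 mutant libraries, peak number and background depth gave Pearson's r = 0.369 (exact permutation p = 0.422) and Spearman's rho = 0.314 (exact permutation p = 0.564), and too few libraries are left to repeat this without the farthest. Of peaks with at least 15 times the background, which depth limits less, WT had 13404 ± 412 (SD, n = 2) and the mutants 17575 ± 1199 (SD, n = 6).

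**Figure D1:**
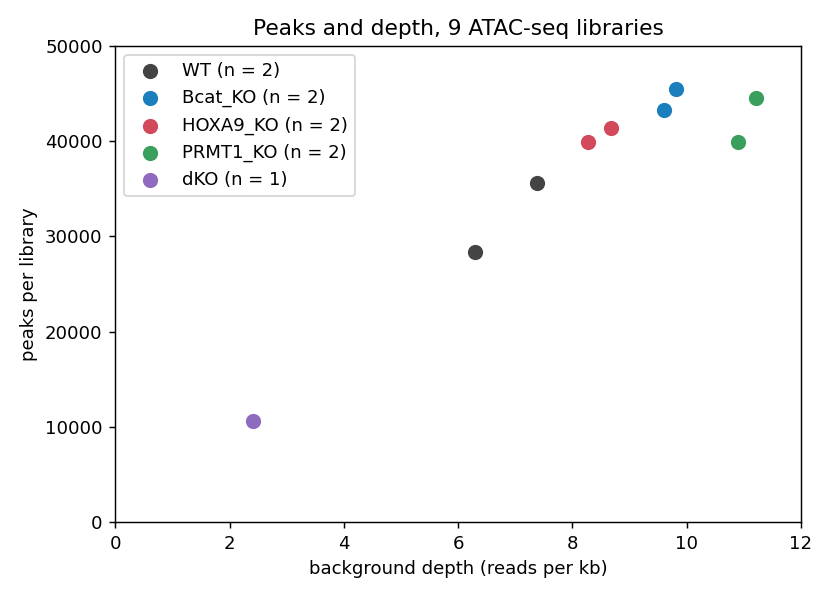
Peaks per library (y axis) against the background depth in reads per kb (x axis) for the 9 ATAC-seq libraries, 1 point per library and 1 colour per group. The 6 single-mutant libraries lie between 39881 and 45460 peaks, both WT libraries below them, and the dKO at 10639 peaks and 2.41 reads per kb.

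The libraries also differed in where their strongest peaks lay. Of the 28325 strongest peaks, 36.2 ± 0.682% (SD, n = 2) lay near a gene end in WT, 34.8 ± 0.215% in Bcat_KO, 35.2 ± 0.382% in HOXA9_KO and 34.3 ± 0.0699% in PRMT1_KO (SD, n = 2 each; exact permutation p = 0.00952, the smallest possible). With the lists as deposited this difference did not pass (exact permutation p = 0.0857). In the dKO, whose whole list is short, 53.3% of peaks lay near a gene end. Chromosome X held 2.75 ± 0.0163% (SD, n = 2) of WT peaks and 2.24 ± 0.0673% (SD, n = 6) of the mutant peaks. On chromosome Y outside its distal end (beyond 90 Mb), which is male-specific, each single-mutant library had 12 to 16 peaks, the dKO had 6 and both WT libraries had 0. Peaks at Xist, the gene that silences the second X of females, numbered 2 in each WT library, 1 in Bcat_KO replicate 1 and 0 in the other libraries. In each comparison of a mutant with WT, a possible difference in sex therefore cannot be told apart from the genotype, on autosomes too.

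Accessible regions grouped by genotype, and the mutants differed among themselves. The 28325 strongest peaks of the paired libraries gave 46847 regions, of which 15951 (34.0%) were in all 8. The Jaccard index within a genotype was 0.713 in Bcat_KO, 0.716 in HOXA9_KO, 0.736 in PRMT1_KO and 0.641 in WT, with a mean of 0.701 against 0.642 between genotypes. No other division of the 8 libraries into pairs exceeded 0.688 (exact permutation p = 0.00952, the smallest possible). Of the 8 libraries, 7 were most like the other of their genotype, and WT replicate 1 was nearer to PRMT1_KO replicate 1 (0.651). Bcat_KO and PRMT1_KO were the most alike pair of mutants, at 0.695 ± 0.0063 (SD over 4 library pairs), followed by Bcat_KO and HOXA9_KO at 0.670 ± 0.0047 and HOXA9_KO and PRMT1_KO at 0.637 ± 0.0057. That order did not pass its test (exact permutation p = 0.0667, 3 of 45 assignments). WT was less like the mutants (0.616, between 0.588 and 0.651 per library pair) than different mutants were like each other (0.667, between 0.629 and 0.702). Without the WT libraries, 15 divisions remain, which cannot give a p under 0.0667, and the division by genotype was the highest of them.

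**Figure D2:**
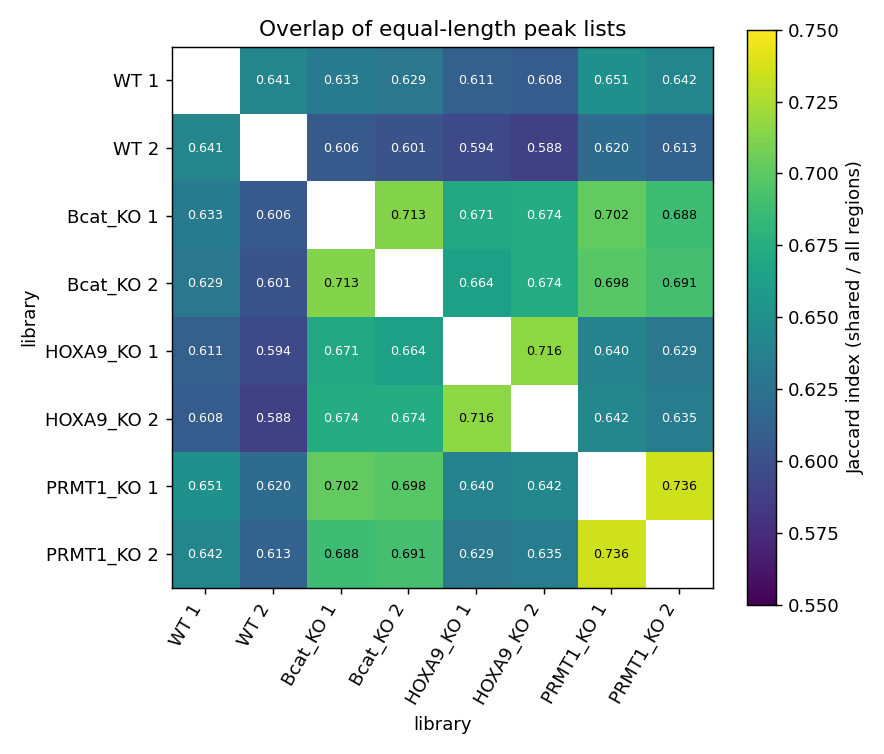
Jaccard index of every pair of the 8 paired libraries (both axes), computed on lists of equal length, as shared regions over all regions. The 3 mutant replicate pairs reach 0.713 to 0.736, and pairs of a WT and a mutant library lie between 0.588 and 0.651.

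In Bcat_KO against WT, which asks what loss of β-catenin changes, 39 regions were closed and 126 opened. Of these, 12 closed and 106 opened regions had no peak in the full lists of the other side. Among the closed regions with the strongest ranks were 1 near Pls3 (chromosome X, 75744350 to 75744954), which encodes an actin-bundling plastin, with a fold over background of 10.2 ± 1.80 (SD, n = 2) in WT and no peak in Bcat_KO. Another lay near Mid1 (chromosome X, 170013269 to 170014491), the gene of a ubiquitin ligase, at 10.2 ± 1.76 (SD, n = 2) in WT and 5.18 in 1 of the Bcat_KO libraries. Autosomal closed regions lay near Marveld2 (10.3 ± 1.39 (SD, n = 2) in WT), Zfp781 (9.57 ± 0.305), Ccdc7a (8.62 ± 1.05) and Klra10 (7.80 ± 0.322), and inside Gadl1 (8.94 ± 0.356) and Chst15 (7.96 ± 0.833). Gadl1 had no peak in Bcat_KO, while the regions at Zfp781, Chst15, Ccdc7a and Klra10 kept weak peaks in both libraries. A closed region without a gene within 50 kb ranked above them (chromosome 3, 140950080 to 140950885; 10.5 ± 1.25 in WT). The strongest opened region was a narrow one near Dpy19l2 (chromosome 9, 24542013 to 24542160) at 44.2 ± 3.47 (SD, n = 2) times background and without a peak in WT. Another narrow one lay near Tra2a, a splicing factor gene (chromosome 6, 49236451 to 49236609), at 21.9 ± 3.89 (SD, n = 2), and others lay inside Fbxw4 (13.3 ± 1.98) and Fyb2 (12.5 ± 1.78). Regions without a gene within 50 kb ranked among the 8 strongest opened ones, starting at 258188 (14.1 ± 0.658) and 11857738 (19.7 ± 1.17) on chromosome Y, at 77438908 on chromosome 13 (19.0 ± 2.39), and at 3022063 (2.13 ± 0.0806) and 3258423 (15.3 ± 2.3) on chromosome 9. Without a filter for repeats, mapping artifacts were not excluded at the narrow regions and at the one with a fold of 2.13. Of the fixed lists, the Wnt target Lef1, which encodes a DNA-binding partner of β-catenin, gained a region inside the gene (chromosome 3, 131157381 to 131157911; 9.66 ± 1.99 (SD, n = 2), no peak in WT). Col1a2, a collagen gene of the stromal list, gained a region 21.2 kb away (10.6 ± 0.710 (SD, n = 2), no peak in WT). Opened regions with a gene nearby were also strong on chromosome Y, at Eif2s3y, Uty, Ddx3y and LOC665918, where WT had no male-specific peak. The mixed splits gave 1 to 6 regions per direction against these 39 and 126, and simulated libraries with no group effect gave at most 19 closed and 18 opened regions. Leaving out each of the 4 libraries in turn gave 100 to 232 closed and 260 to 378 opened regions, and with the lists as deposited the 648 closed regions lay below the highest mixed split (1637).

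In HOXA9_KO against WT, which asks what loss of Hoxa9 changes, 75 regions were closed and 209 opened, the highest counts of the 3 mutants at equal list length. Of these, 29 closed and 174 opened regions had no peak in the full lists of the other side. With the lists as deposited, the 4978 opened regions of HOXA9_KO were the lowest of the 3. The strongest closed region lay inside Xrcc4 (chromosome 13, 89888958 to 89889577), a gene of DNA double-strand break repair by end joining, at 14.2 ± 1.54 (SD, n = 2) times background in WT. In HOXA9_KO it had no peak in 1 library and a weak one of 3.19 in the other. Other closed regions lay near Pls3 (10.2 ± 1.80 (SD, n = 2) in WT) and inside Nxf3 on chromosome X (9.69 ± 1.97), both without a peak in HOXA9_KO. Others lay at Fhad1 (7.88 ± 0.958), Cyp4a12a (9.37 ± 0.394), Zfp600 (9.30 ± 0.618), Ipmk, an inositol phosphate kinase gene (9.24 ± 2.30), and Pla2g4a, the gene of cytosolic phospholipase A2 (8.16 ± 0.514). Without a gene within 50 kb, closed regions starting at 134339214 (9.49 ± 0.288) and 143147437 (9.48 ± 0.164) on chromosome 3 were also among the 8 strongest. Among the opened regions with strong ranks were those inside Vmp1, a gene of autophagy (chromosome 11, 86592884 to 86593556; 13.9 ± 0.447 (SD, n = 2)), Nav3 (11.9 ± 0.984) and Tpd52 (10.6 ± 2.99). Each of these had no peak in WT. Of the fixed lists, 2 Wnt targets gained regions: Lef1 (10.4 ± 0.161 (SD, n = 2)) and Lgr5, a receptor for R-spondins, with regions at 115465699 to 115466353 (9.05 ± 0.101) and at 115518568 to 115519373 (8.69 ± 0.344) on chromosome 10. Rab27b of the megakaryocyte list, a gene of granule secretion, gained a region inside it (10.5 ± 0.396). Regions on chromosome Y at Ddx3y (15.3 ± 2.30), Uty (14.8 ± 2.05) and Eif2s3y (15.8 ± 1.22), where WT had no male-specific peak, were opened as well. Without a gene within 50 kb, opened regions starting at 93254179 on chromosome 7 (17.2 ± 1.75), 67677556 on chromosome 4 (14.1 ± 0.803), and 258188 (11.1 ± 0.481) and 11857738 (16.2 ± 2.25) on chromosome Y were among the 8 strongest. The mixed splits gave 1 to 7 regions per direction, and simulated libraries with no group effect at most 17 in each. Leaving out each of the 4 libraries in turn gave 146 to 314 closed and 372 to 484 opened regions, and with the lists as deposited the 1087 closed regions lay below the highest mixed split (1445).

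In PRMT1_KO against WT, which asks what loss of Prmt1 changes, 33 regions were closed and 88 opened. Of these, 14 closed and 74 opened regions had no peak in the full lists of the other side. Closed regions lay near Pls3 (10.2 ± 1.80 (SD, n = 2) in WT), at 2 sites near Mid1 (10.2 ± 1.76 and 8.04 ± 0.610) and near the end of Spin2c (8.0 ± 0.672), all on chromosome X and without a peak in PRMT1_KO. Autosomal closed regions lay inside Tbck (9.58 ± 1.72), Shld1, a gene of the shieldin complex that protects DNA ends (chromosome 2, 132695641 to 132696189; 7.93 ± 0.112), and Ryr3, a calcium channel gene (7.88 ± 0.453), also without a peak in PRMT1_KO, and near Speer4c (6.34 ± 0.452). Without a gene within 50 kb, regions starting at 15506962 (6.09 ± 0.724) and 15039733 (6.43 ± 0.347) on chromosome 5, 144406579 on chromosome 1 (8.92 ± 2.41) and 87009357 on chromosome 18 (8.68 ± 0.261) were among the 8 strongest closed ones. Opened regions with strong ranks lay near Dpy19l2 (46.7 ± 3.41 (SD, n = 2)) and Tra2a (19.5 ± 0.170), and inside Fbxw4 (16.4 ± 3.44) and Fyb2 (13.9 ± 1.54). Each was also opened in Bcat_KO. From the fixed lists, Lef1 had an opened region (11.1 ± 1.47 (SD, n = 2)). In addition, gene ends were opened at Rfc3, a subunit of the replication clamp loader (chromosome 5, 151642734 to 151643202; 9.24 ± 0.343), and at Bax, a pro-apoptotic p53 target (chromosome 7, 45460894 to 45461321; 5.81 ± 0.0278). Both gene ends had peaks in 6 of the 8 libraries and none in WT. Ddx3y (16.4 ± 3.38), Uty (16.2 ± 0.322), Eif2s3y (15.9 ± 2.93) and a region near LOC665918 (12.8 ± 1.84) were opened on chromosome Y, where WT had no male-specific peak. Without a gene within 50 kb, opened regions starting at 77438908 on chromosome 13 (21.3 ± 1.59), at 258188 (13.6 ± 0.959) and 11857738 (20.3 ± 2.05) on chromosome Y and at 3022063 on chromosome 9 (2.04 ± 0.0884) were among the 8 strongest. Mapping artifacts were not excluded at the last of these, nor at the narrow regions near Dpy19l2 and Tra2a. The mixed splits gave 1 to 3 regions per direction, and simulated libraries with no group effect at most 22 closed and 17 opened, so the 33 closed regions exceed that level by little. Leaving out each of the 4 libraries in turn gave 75 to 220 closed and 207 to 349 opened regions, and with the lists as deposited the 664 closed regions lay below the highest mixed split (1800).

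**Figure D3:**
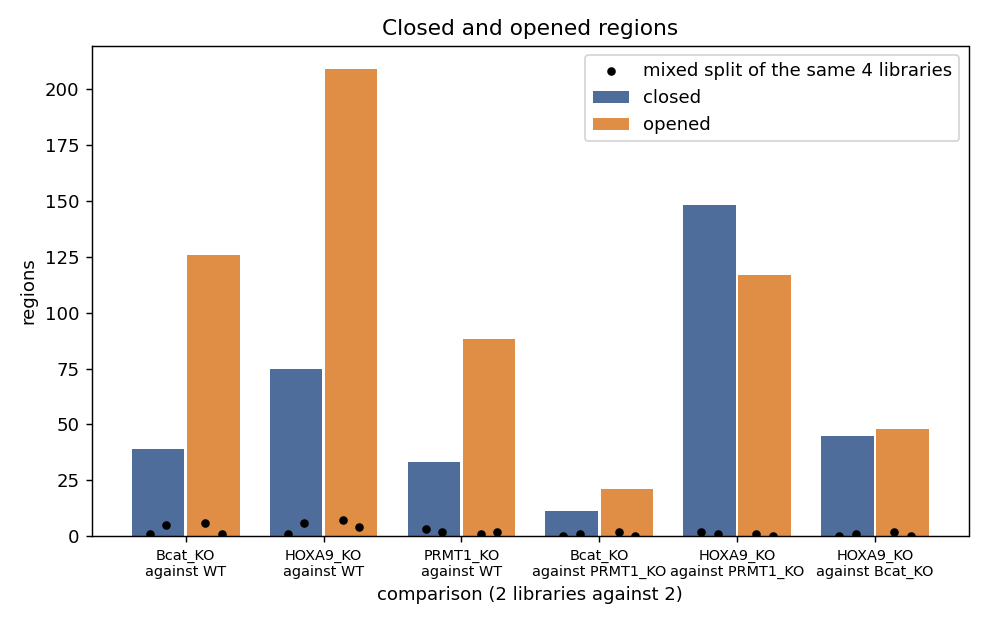
Number of closed and opened regions (y axis, bars) in each comparison of 2 libraries against 2 (x axis), with the counts of both mixed splits of the same 4 libraries as points. The real counts run from 11 to 209 and the mixed splits from 0 to 7.

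A set of regions separated both WT libraries from all 6 mutant libraries, the question of a change common to the 3 mutants. In the mutants alone, 19 regions were open, 8 of them on chromosome Y and 11 on autosomes, and 18 of the 19 had no peak in the full WT lists. The named autosomal ones lay inside Vmp1 (12.1 ± 1.80 (SD, n = 6)), Chd7, a chromatin remodeller gene (12.3 ± 0.948), Uchl5, a proteasomal deubiquitinase gene (12.4 ± 1.21), Lef1 (10.4 ± 1.29), Hey1, a Notch target (7.6 ± 0.500), and Jmjd1c, a histone demethylase family gene (6.83 ± 1.15). Others lay near Pan3 (7.16 ± 0.956), Srd5a2 (11.3 ± 1.40) and Ostf1 (10.5 ± 0.985). On chromosome Y the ends of Ddx3y (15.3 ± 2.21 (SD, n = 6)), Uty (15.5 ± 1.71) and Eif2s3y (15.5 ± 1.54) were open in all 6 mutant libraries. The WT libraries, which had 0 male-specific peaks, differed from the mutants in this as well. In WT alone, 7 regions were open, 4 of them on chromosome X, including those near Pls3 and Mid1, and 3 on autosomes, including those at Slc4a7 (7.39 ± 0.68 (SD, n = 2)) and Dock9 (7.18 ± 0.512). Of the 28 choices of 2 libraries from 8, 2 gave as many regions as the 26 of WT (share 0.0714), and on autosomes 14 regions remained. Genes of this paragraph that the rule does not name were given because their count was low, after their values were seen.

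The changed regions of the 3 mutants overlapped. Bcat_KO and HOXA9_KO shared 13 closed and 41 opened regions, Bcat_KO and PRMT1_KO 16 and 34, and HOXA9_KO and PRMT1_KO 12 and 27. In the simulated libraries with no group effect that shared their WT libraries, the highest overlaps in 100 draws were 10 closed and 2 opened regions. Of the shared opened regions, 8 in each pair were on chromosome Y, and of the shared closed ones 4, 5 and 4 in the same order were on chromosome X, where a difference in sex could act as well. On autosomes 9, 11 and 8 shared closed regions were left against simulated highs of 8, 10 and 8, so the closed overlap hardly exceeded the level without an effect. The 32, 26 and 19 shared opened regions on autosomes exceeded their simulated highs of 2, 1 and 1. In all 3 mutants, 7 regions were closed and 19 opened. The simulation kept the shared WT libraries but not the lack of male-specific peaks in WT. Having no group effect, it also left out the lower depth of WT (6.29 and 7.38 reads per kb) and its lower Jaccard index within the genotype (0.641). Whether these alone give shared opened regions was not tested.

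HOXA9_KO and PRMT1_KO, the least alike mutants, both carried the male-specific peaks and differed at 265 regions, 148 lower and 117 higher in HOXA9_KO. Lower in HOXA9_KO were regions inside Mid1 (16.5 ± 0.510 (SD, n = 2) in PRMT1_KO; 4.81 and 5.01 in HOXA9_KO), Xrcc4 (14.9 ± 3.12 in PRMT1_KO), Fyb2 (13.9 ± 1.54), Pik3ap1, an adaptor gene of phosphoinositide 3-kinase signalling (11.6 ± 0.225), and Lrrc72 (11.9 ± 0.531). Others were near Adam17, a shedding protease gene (12.2 ± 0.962), Klhl2 (14.5 ± 0.257) and Etv6, an ETS transcription factor gene of the stem cell list (chromosome 6, 134020532 to 134021303; 13.6 ± 4.05). Pold1 of the replication list, the catalytic subunit of DNA polymerase delta, had a lower region inside the gene (7.70 ± 0.0336). Higher in HOXA9_KO were regions inside Nav3 (11.9 ± 0.984 (SD, n = 2) and 11.8 ± 0.125 in HOXA9_KO), Dcbld1 (11.7 ± 1.04), Tmtc2 (11.8 ± 0.0277), Lhcgr (10.6 ± 2.30) and Lgr5 (9.05 ± 0.101 and 8.69 ± 0.344), and a region near Fam181b (13.5 ± 4.38). Of the 117 higher regions, 34.2% lay over 50 kb from a protein-coding gene, against 8.72% of unchanged regions of like rank, and 3.42% lay near a gene end against 42.5%. The unchanged regions were open in all 8 libraries, so this contrast sets variable regions beside constant ones. The mixed splits gave 0 to 2 regions per direction, and simulated libraries with no group effect at most 15 lower and 19 higher.

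HOXA9_KO also stood out when each genotype was set against all others. It had 22 regions that no other library had among its strongest 28325 peaks and lacked 9 that all 6 other libraries had. Among the 22 were Fstl5 (12.1 ± 0.898 (SD, n = 2)), Adgrv1 (10.1 ± 0.0816), Camk2d (9.48 ± 0.754) and Lgr5 (8.69 ± 0.344). Among the 9 were Xrcc4 (13.1 ± 2.72 (SD, n = 6) in the others), Pik3ap1 (9.97 ± 1.83), Apbb1ip (9.83 ± 1.45) and Trit1 (7.49 ± 0.95). No other choice of 2 libraries gave as many as these 31 (exact share of 28 choices 0.0357, the smallest possible). HOXA9_KO was singled out because it ranked first, and some choice must rank first, so this share does not test it in particular. Bcat_KO had 5 regions that no other library had among its strongest 28325 peaks, at Cks1brt (14.1 ± 0.275 (SD, n = 2)), Heatr3 (13.0 ± 4.93), Csgalnact1 (10.7 ± 2.23), Kif5c (9.82 ± 0.906) and a site without a gene within 50 kb. PRMT1_KO had 3, of which 1 lay inside Lyn, a Src family kinase gene (9.54 ± 0.367 (SD, n = 2)). The genes named for single genotypes were chosen after their values were seen. Over the 4 genotypes the regions open in a single genotype numbered 37, and no other division gave more than 30 (exact permutation p = 0.00952, the smallest possible).

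Bcat_KO and PRMT1_KO differed least, at 32 regions. Lower in Bcat_KO were regions inside Lyn (9.54 ± 0.367 (SD, n = 2) in PRMT1_KO), Lrrc17 (10.4 ± 0.472), Vopp1 (7.85 ± 0.524) and Wwox (7.93 ± 0.454), and near Spin1 (10.2 ± 0.517) and Tnfsf9 (8.85 ± 0.148). Higher in Bcat_KO were regions at Cks1brt (14.1 ± 0.275 in Bcat_KO), Heatr3 (13.0 ± 4.93), Speer4d (10.1 ± 2.07), Polr3g, an RNA polymerase III subunit gene (9.90 ± 0.165), and Slc49a4 (9.23 ± 0.244). These were 11 lower and 21 higher regions, against 0 to 2 in the mixed splits. Simulated libraries with no group effect gave up to 18 in each direction and at least 11 lower ones in 32 of 100 draws, so the lower regions cannot be told from that level and the higher ones exceed it by little. With close summits merged, the margin shrank to 119 and 133 regions against up to 116 in a mixed split, and in the lists as deposited to 1739 and 1996 against up to 1737. HOXA9_KO and Bcat_KO differed at 93 regions, 45 lower and 48 higher in HOXA9_KO. Lower regions were inside Arhgap10 (12.3 ± 0.0132 (SD, n = 2) in Bcat_KO), Fyb2 (12.5 ± 1.78) and Pik3ap1 (10.2 ± 2.18), and near Tfcp2l1 (10.9 ± 0.985) and Tgfb2, a growth factor gene (10.4 ± 0.388). Higher regions included one at the end of Khdrbs2 (11.8 ± 1.66 in HOXA9_KO), one inside Lonrf1 (11.5 ± 1.43), and others outside Rnf125, 5.9 kb away (11.9 ± 0.761), and Mcm9, a helicase gene of recombination repair, 32.8 kb away (9.80 ± 0.103). The mixed splits gave 0 to 2 regions per direction here as well, and simulated libraries with no group effect at most 19 lower and 21 higher. With close summits merged the counts were 156 and 166 against up to 118 in a mixed split.

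Changed regions lay away from gene ends, and few genes of the 18 fixed lists were among their neighbours. Near gene ends were 7.14% of the regions opened in Bcat_KO, 6.70% in HOXA9_KO and 11.4% in PRMT1_KO, against 43.0%, 42.7% and 44.7% of unchanged regions of like rank. The unchanged regions were open in all 8 libraries. The contrast thus sets variable regions beside constant ones and shows nothing particular to the mutants. Of the Wnt targets, Lef1 had an opened region in all 3 mutants and Lgr5 in HOXA9_KO. DNA replication had Rfc3 and p53 targets had Bax, both called in PRMT1_KO. The gene ends of both had peaks in all 6 mutant libraries and none in WT, so these peaks were not particular to PRMT1_KO. The megakaryocyte markers had Rab27b in HOXA9_KO, and the stromal and endothelial markers had Col1a2 in Bcat_KO. In 12 lists there was no closed or opened region against WT. They were the targeted genes, stem cell regulators, DNA damage repair genes, the Hox cluster, arginine methyltransferases, housekeeping genes, and the myeloid, erythroid, B lymphoid, T and NK lymphoid, mast and eosinophil, and dendritic cell markers. In the test of gene ends against random lists, Bax (share of random lists 0.0080, adjusted 0.864) and Rfc3 (0.0191, adjusted 1) were the only members found, and 0 of 108 tests passed. At p under 0.05 without adjustment, those 2 lists were the ones that passed.

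The dKO, labelled as the double mutant of β-catenin and Hoxa9, was compared with the single mutants at the regions that set them apart. Of the regions higher in HOXA9_KO than in PRMT1_KO, 29.9% (35 of 117, 95% Wilson interval 22.4 to 38.7%) had a dKO peak, and of those lower in HOXA9_KO, 2.70% (4 of 148, 1.06 to 6.74%; Fisher's exact p = 2.1e-10, adjusted p = 1.26e-09). Unchanged regions of like rank, which were open in all 8 libraries, gave 36.8% and 33.4%. Of these, 42.5% and 40.8% lay near a gene end, against 3.42% and 2.03% of the changed regions. They therefore cannot show whether the contrast came from the higher or the lower regions. Among the higher regions with a dKO peak were a Nav3 region (5.67 in the dKO) and an Lgr5 region (4.48), and among the lower ones Mid1 (4.88). The regions that set HOXA9_KO apart from Bcat_KO gave 27.1% for higher and 2.22% for lower ones (Fisher's exact p = 8.65e-04, adjusted p = 0.0026), with dKO peaks at Khdrbs2 (7.36) and Mcm9 (7.21). Against WT, 19.1% of the regions opened in HOXA9_KO and 8.0% of those closed had a dKO peak (Fisher's exact p = 0.0277, adjusted p = 0.0416). For PRMT1_KO the order was the other way, with 9.09% of opened and 27.3% of closed regions (Fisher's exact p = 0.0172, adjusted p = 0.0344). Bcat_KO against WT (11.9% of opened and 20.5% of closed regions, Fisher's exact p = 0.191, adjusted p = 0.229) and Bcat_KO against PRMT1_KO (p = 0.637, adjusted p = 0.637) did not pass. At equal length, the dKO list was about as like WT (Jaccard index 0.456 ± 0.0068, SD, n = 2) as it was like HOXA9_KO (0.451 ± 0.0050), and less like Bcat_KO (0.432 ± 0.0032) and PRMT1_KO (0.426 ± 0.0025). Background depth rose in the same order (means of 6.83, 8.47, 9.71 and 11.1 reads per kb), and the dKO was the shallowest library. For this order, depth and genotype cannot be told apart. The shares of changed regions with a dKO peak followed depth as well. In each comparison but HOXA9_KO against WT, the higher share was at the regions open in the shallower genotype. Depth and genotype were thus not separated for these shares either. These tests run across regions of a single library, which are not replicates, and at its depth of 2.41 reads per kb a missing peak was not detectable and not shown to be absent.

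**Figure D4:**
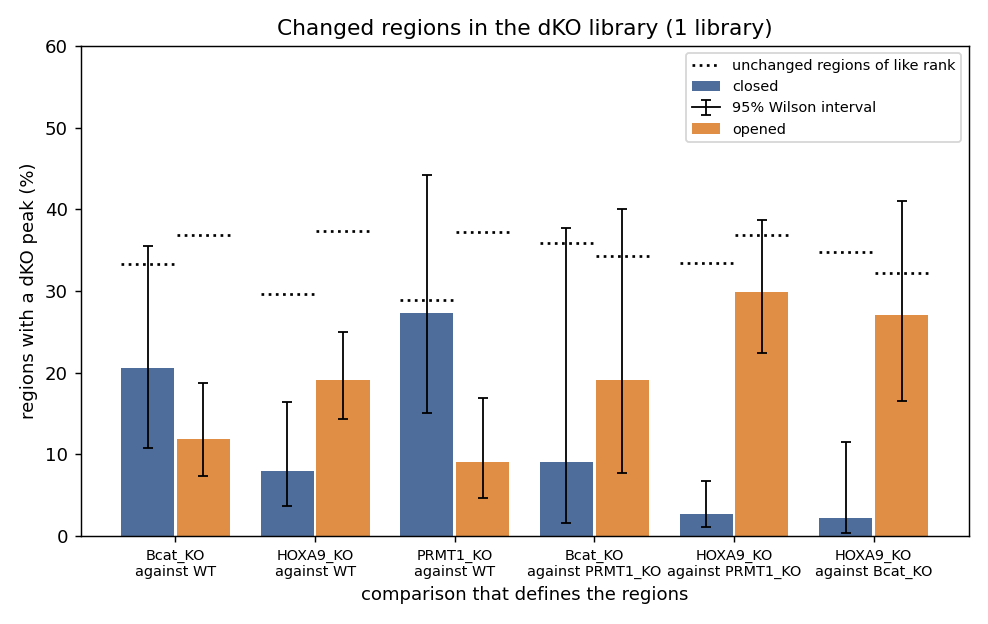
Percent of the closed and opened regions of each comparison (x axis) that had a peak in the single dKO library (y axis), with 95% Wilson intervals. Dotted lines show unchanged regions of like rank that were open in all 8 paired libraries. Of the regions of HOXA9_KO against PRMT1_KO, 29.9% of those higher in HOXA9_KO and 2.70% of those lower had a dKO peak.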

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

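Among the tests of this part, the one of depth for the peak number was set before its result was seen, and all others were chosen only after it.

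HOXA9_KO had or lacked 31 regions that set it apart from all 6 other paired libraries, a difference between groups that no other choice of 2 of the 8 libraries reached (26 for WT, 5 for Bcat_KO, 3 for PRMT1_KO, and at most 2 for a mixed pair). The dKO library, which none of the comparisons between groups uses, held 6 peaks on the male-specific part of chromosome Y, where the WT libraries held 0.

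The first pattern is the lower number of peaks in WT than in the 6 single-mutant libraries. Sequencing depth predicts that peaks at 15 times the background, which every library can call, do not separate them, but WT had 13404 of these on average and the lowest mutant library 16206, which argues against depth as the whole cause. The fragment length used in peak calling was longer in WT (173.5 bp on average) than in any mutant (126 to 153 bp). Within the 6 mutants it was not related to the number of such peaks (Spearman's rho = 0.0286, exact permutation p = 1), and since it separates the groups it cannot be told apart from the genotype. The sex of the cells, the transplantation history and the genotype itself stay open as untested explanations.

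The second pattern is the set of regions that separates WT from all 6 mutants. Of the 8 regions on chromosome Y in this set, 100% lay outside the distal end and had no WT peak, which is consistent with a difference in sex between the cells of WT and of the mutants. For the 14 autosomal regions, among them those at Lef1, Vmp1 and Chd7, sex and genotype cannot be told apart, because 0 WT libraries carried male-specific peaks and so no WT library of the other sex was there to compare. The same limit holds for every autosomal region that changed in a mutant against WT. A shared effect of the mutations therefore stays open beside sex, a strain variant and the transplantation history, the last 2 of which were not tested.

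The third pattern is the difference between HOXA9_KO and PRMT1_KO, at Xrcc4, Etv6, Nav3 and Lgr5 among other regions. The sex of the animals is argued against, since both genotypes carried male-specific peaks and 1.13% of the regions lay on X and Y. So is depth as the whole cause, since of the 114 regions without any peak in the full, unshortened lists of the other genotype, 51.8% were open in HOXA9_KO, the shallower one. An altered segment around Hoxa9 or a segment that differs between the strains anywhere else is also argued against as the whole cause. Of all the regions, 2.64% (7) lay within 20 Mb of Hoxa9. No window of 20 Mb held more than 3.82% of the autosomal ones (10 regions). These shares cannot exclude a segment behind a part of the regions. Of the 116 autosomal regions higher in HOXA9_KO, 8 lay in 1 such window on chromosome 10, among them those at Tmtc2, Nav3 and Lgr5. This gathering did not pass the correction (share of random draws 0.0145, adjusted 0.0870), and a segment there was not tested. An effect of the genotype on chromatin may underlie the regions that differ. Variants scattered over the genome and library batches, which the labels do not give, were not tested. A different mix of cell types within the LSK gate stays open. Regions near myeloid markers numbered 22 and 22 in HOXA9_KO and 29 and 27 in PRMT1_KO. B lymphoid markers had 19 and 16 against 25 and 22, and dendritic cell markers 19 and 18 against 25 and 23. Counts of the other lineage lists overlapped or met. These lists did not pass over the genotypes (exact permutation, adjusted p = 0.286 each), so the counts do not decide whether the mix differed.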

How the results depend on the processing

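Absence from the full lists, the tests without WT, the simulated counts for comparisons between mutants, the simulated overlap on autosomes and the alternatives for the similarity among mutants and for dKO peaks were chosen only after the results were seen. Of the alternative values, 88 kept their direction and their side of the threshold or moved little, 3 were weaker, 5 stronger, 64 moved and 0 reversed. In 39 of 42 combinations of an alternative and a comparison, both directions exceeded the highest mixed split, and the exceptions were the 3 closed counts against WT in the lists as deposited. In the main setting the mixed splits gave at most 7 regions, while simulated libraries with no group effect gave up to 22. A count above the mixed splits can thus lie within the level without an effect, and no simulation was run for the alternatives. The margin was thin for Bcat_KO against PRMT1_KO, where the larger direction was only 1.15 times the highest mixed split with summits merged (119 and 133 regions against 116) and also as deposited (1739 and 1996 against 1737), down from 10.5 times in the equal lists. Beside simulated libraries with no group effect, its 11 lower regions lay within the level without an effect (up to 18), and its 21 higher ones just above (up to 18). For HOXA9_KO against Bcat_KO the larger direction was 1.41 times the highest mixed split with summits merged. The difference in dKO peaks between regions higher and lower in HOXA9_KO than in PRMT1_KO passed under all 7 alternatives (Fisher's exact p from 1.33e-43 to 2.26e-05). None of these alternatives separates depth from genotype. Motif tests and their alternative window were not run for want of a genome sequence. A peak missing from a list is limited by depth, which was lowest in the dKO (2.41 reads per kb) and in WT (6.29 and 7.38), so a count of closed or opened regions cannot separate a closed region from one not detectable. Where no cause is given below, the cause was not tested.

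Replicate numbers did not pair the libraries, since the difference between numbers 1 and 2 of a genotype, over the 15951 regions in all 8 libraries, correlated with that of another genotype at 0.00458 to 0.0404, above 0.1 in 0 of 6 pairs of genotypes. With the replicate block, that is the 24 divisions that keep number 1 with number 2, the similarity of peak sets, the genotype-specific regions and the share near gene ends each gave an exact permutation p of 0.0417, the smallest possible, and the peak number gave 0.167. Without the WT libraries the similarity and the genotype-specific regions each gave 0.0667, the smallest of 15 divisions, so fewer samples are the cause.

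With the lists as deposited, which hold more and weaker peaks by construction, there were 2354 genotype-specific regions (37 in the equal lists), 1482 that separated WT (26 in the equal lists; exact share of 28 choices 0.0357), and 7420 overlaps between mutants (143 in the equal lists). Closed and opened regions numbered 648 and 5445 in Bcat_KO, 1087 and 4978 in HOXA9_KO, and 664 and 5048 in PRMT1_KO, and PRMT1_KO differed from Bcat_KO at 3735 and from HOXA9_KO at 6318 regions. The share of peaks near gene ends then gave an exact permutation p of 0.0857, and the mean Jaccard index of the dKO with the others fell from 0.441 to 0.229. With a −log10 q-value of at least 5, the peak number gave an exact permutation p of 0.0381.

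With the list length halved, which leaves fewer peaks, these counts were 10 genotype-specific and 9 separating regions (share 0.0357), 7 and 46 in Bcat_KO, 20 and 58 in HOXA9_KO, 5 and 36 in PRMT1_KO, and 9 and 87 between PRMT1_KO and Bcat_KO or HOXA9_KO. With no gap between the cutoffs they were 1847 and 1079 (share 0.0357), 1658 and 2066, 1932 and 2496, 1533 and 1979, and 2391 and 4542, in the same order. With summits within 100 bp merged they were 145 and 121 (share 0.0357), 195 and 325, 244 and 421, 204 and 285, and 252 and 534. On autosomes alone, 14 regions separated WT from the mutants. Requiring absence from the full lists left 12 closed regions in Bcat_KO, 29 in HOXA9_KO and 14 in PRMT1_KO, and 16 and 114 between PRMT1_KO and Bcat_KO or HOXA9_KO.

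Leaving out 1 library in turn, with the single library left standing for its genotype, gave 100 to 232 closed and 260 to 378 opened regions in Bcat_KO, 146 to 314 and 372 to 484 in HOXA9_KO, and 75 to 220 and 207 to 349 in PRMT1_KO. Counts rise by construction, since fewer libraries must meet the rule.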

Other observations

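The counts of regions near gene lists and in windows of the genome were chosen only after the data were seen, and the test of the chromosome 8 segment was set before its own result was seen.

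Regions at or near the erythroid markers among the strongest 28325 peaks were more numerous in WT than in the mutants, at 22.5 ± 0.707 (SD, n = 2) against 15.7 ± 1.21 (SD, n = 6). The regions of Klf1, the erythroid master regulator, of Epor, the erythropoietin receptor, and at the ends of Tfrc, the transferrin receptor, and Icam4 were in all 8 libraries. The excess in WT came largely from regions seen in no mutant, at Rhd, Alas2, Trim10, Hba-a1, Hbb-bs, Aqp1 and Car2, among others. Apart from an Aqp1 region (chromosome 6, 55358749 to 55359146) that both WT libraries had, each of these was in only 1 WT library. It did not pass the correction over the 18 lists (exact permutation p = 0.019, adjusted p = 0.257; share of the 28 choices 0.0357, adjusted 0.643). Regions near p53 targets numbered 38.5 ± 2.12 in PRMT1_KO, 36.0 in both HOXA9_KO libraries, 35.5 ± 0.707 in WT and 34.0 in both Bcat_KO libraries (SD, n = 2 each; exact permutation p = 0.0286, adjusted p = 0.257). Mast and eosinophil markers had 1.5 ± 0.707 regions in Bcat_KO, 5.5 ± 0.707 in HOXA9_KO, 6.5 ± 0.707 in PRMT1_KO and 3.5 ± 2.12 in WT (SD, n = 2 each; exact permutation p = 0.0762, adjusted p = 0.286). The adjusted p over the divisions ran from 0.257 to 0.857 over the 18 lists, and 0 lists passed.

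Regions that differed between Bcat_KO and HOXA9_KO gathered on chromosome 8. Between 68.6 and 88.2 Mb lay 9 of the 92 autosomal regions, at Csgalnact1, Slc35e1, Arhgap10, Frem3, Inpp4b, Rnf150, Tbc1d9, Cks1brt and Heatr3, of which 5 were open in Bcat_KO and 4 in HOXA9_KO. Of 2000 random draws of as many regions, the highest held 8 in a window of 20 Mb (share 0.0005, the smallest these draws can give; adjusted 0.0090 over 18 searches). A candidate explanation is a chromosome segment that differs in Bcat_KO from the other genotypes, for instance from another mouse strain. It predicts that both PRMT1_KO libraries side with HOXA9_KO, which they did in 55.6% of the regions (5 of 9), a share between what the segment and its absence call for, so the test decides nothing. The regions of Bcat_KO against PRMT1_KO gathered in a window from 15.6 to 21.6 Mb on chromosome 5, with 5 of 32 regions, among them those at Speer4d, Gsap and Lrrc17 (share of random draws 0.0045, adjusted 0.0405). Of these, 3 higher in Bcat_KO lay close together between 15.55 and 15.71 Mb, and the random draws treat such neighbours as independent. Without a filter for repeats, mapping artifacts were not excluded there.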
